A study of Pimephales promelas with 60 samples.

How the data were processed

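Liver RNA of 60 male fathead minnows was measured on 60 one-colour arrays, 1 fish per array, in 12 groups of 5 (control or RDX, at 1 day and 1, 3, 6, 9 and 12 months). Per the labels' protocols, livers were kept in RNAlater and 0.5 µg of RNA was labelled with Cy3. Per the file headers, the arrays (design Agilent-019597) were scanned on a GenePix 4000A at 5 micron and read with Agilent Feature Extraction 9.5.1.1, protocol GE1-v5_95_Feb07. Per the file headers, the spot intensity used here, the processed signal, was spatially and multiplicatively detrended, with background subtraction off and surrogate values in place of signals near background, and it saturated at 65502. The deposited intensity files were not normalized between arrays. The authors also deposited a table of log2 values. Set against the scanner files over 15208 probes, each of its columns was the log2 processed signal shifted by 1 constant per array, with each probe then centred on its median over the arrays (slope 1, largest residual 3e-06). Shift and 75th percentile summed to the same value within 0.0156 log2 units over the arrays. Its column medians ran from -0.747 to 1.87, and its scale, centring and direction are therefore known; it was used as an alternative.

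Each array had 15744 spots, of which 536 were control spots (77 of them negative controls) and were left out. The other 15208 probes had 1 spot each. In the main setting, the log2 processed signal of each array was reduced by its 75th percentile over these probes. A probe was tested when it was well above background on at least 4 of 5 arrays of at least 1 group, which 10285 probes (67.6%) met. Spots marked as not uniform were treated as missing (1.07% of the tested spots), and 166 probes with fewer than 2 remaining spots in some group were left out, so that 10119 probes were tested. The limit of 2 spots was set at 3 at the start and changed to 2 before the final comparisons, after the data had been seen. Saturated spots were kept, and 2443 tested probes were saturated on at least 1 array.

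All 60 arrays entered 1 limma fit with a mean per group, moderated by eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 48 residual degrees of freedom and a prior of 3.22. Fixed before the data were examined were RDX against control at each time, the mean of the 6 differences, the interaction of RDX with time, each later time against 1 day in control males, the F-test over times in control males and the correlation of RDX differences between times. Added after the data were seen were the same time comparisons in RDX males, 1 month against the mean of the other 5 times, the F-test of RDX at any time, the overlap of the arms, the score per fish, the matching of time profiles, the clusters of probes that varied between fish and the probes that were on in some fish and off in others. The score was tested with exact permutation tests.

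The samples' slides were taken from the labels: 8 slides of 4 to 8 arrays, each scanned on its own, each holding 4 to 8 of the groups, and each group spread over at least 3 slides. Slide was therefore tested as a block. The alternatives were quantile normalization, scaling by the median, normexp background correction (offset 50) with quantile normalization, the authors' log2 table, no filter on dim probes, a filter of 54 of 60 arrays, slide as a fixed block, array weights, a fit of only the groups compared and leaving out each array in turn. Chosen after seeing the data were a fit with the non-uniform spots kept and a fit without the 5 arrays whose 75th percentile lay over 1.5 log2 units from that of the median array, a limit also set after seeing the data. The lowest correlation of log2 signals between 2 arrays was 0.387 and the highest 0.983, and no 2 arrays held identical values. Over the 55 arrays of usual brightness, 154 contigs had 2 tested probes. After group means were subtracted, the median r of these pairs over arrays was 0.199, against 0.00454 for random pairs, and 18.8% had an r above 0.5. In 10 of these contigs a probe was called at 1 month against 1 day in either arm. In 9 of the 10 both probes had the same direction over both arms, and in 0 were both called.

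The description of all 15208 probes in the files is "Unknown". A gene table of assembly fPimPro1.hap1.1 (64593 genes) matched 0 of the probe names, since 78.0% of the probes were named for a contig and 3309 for a GI number that the table does not list. The 31 gene lists fixed before the data were examined could therefore not be tested and none has a result. The rule for named genes was, for each time and for the mean over times, the 5 with the largest rise and fall among those that pass or, where none passes, the 5 with the smallest p in each direction; for the interaction and for time in control males, the 10 with the smallest adjusted p; and members of the lists spoken of. It asked for genes with a usable symbol, and without names it was reduced, for the mean over times and for time in control males, to the first 2 higher and the first 2 lower probes. Probes outside it are named as such.

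The fits were tested on simulated data made from the probe means and shuffled residuals of the 10119 tested probes, with 200 probes changed by known amounts. For RDX against control at 1 time, 2-fold changes were recovered for 0.5% to 12.5% of the changed probes and 4-fold changes for 49.5% to 63%, with 0 calls in the wrong direction. With nothing changed, 0 probes were called in each of the 7 comparisons, in 1 simulation each with residuals shuffled over all groups. Splits of the real arrays within a time, given below, called probes more often. For RDX against control, 7, 5, 32, 18, 0 and 0 of 100 splits called at least 1 probe at 1 day and 1, 3, 6, 9 and 12 months. For the mean over times 0 did. False calls among the unchanged probes numbered 0 to 14, except in 1 simulation of a 2.83-fold change at 6 months, which gave 251. For the F-test over times in control males, a 4-fold change at 1 month was recovered for 56% of the changed probes, with 3 other calls. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.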

Results

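The data were one-colour microarray measurements of liver RNA from 60 adult male fathead minnows (*Pimephales promelas*), a small freshwater fish used in aquatic toxicology. Exposed fish lived in water holding RDX (hexahydro-1,3,5-trinitro-1,3,5-triazine), a nitramine explosive that enters water from munitions sites, at a mean of 0.83 mg/L with an SD of 0.15 mg/L. Males were taken at 1 day and at 1, 3, 6, 9 and 12 months, 5 exposed and 5 control males each time, so that 12 groups of 5 arrays were compared. Each condition had 8 tanks of 2 males and 4 females, and males were drawn from the tanks with replacement. The labels do not say which tank a fish came from, so fish of one group may share a tank, and p-values measure the spread among these samples. Each array held 15208 non-control probes of 60 bases, designed on 14499 contigs or expressed sequence tags. The files do not pair the probes with genes, so every result is given for probes, with the sequence of each named probe.

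The share of probes well above background ran from 20.5% to 81.4% over the 60 arrays, with a median of 62.3%. The arrays differed in brightness before scaling, measured as the 75th percentile of the log2 signal. The array of control 1 day replicate 5 was 18.5-fold dimmer than the median array, and 4 arrays were 3.26-fold to 7.97-fold brighter: control 9 month replicate 5, control 3 month replicate 5, RDX 3 month replicate 2 and control 6 month replicate 3. The other 55 arrays lay between 0.384 and 2.22 times the median array. On control 1 day replicate 5, 4714 of the 10119 tested probes held 1 shared value, -1.68 on the scaled log2 scale. The scanner software puts it in place of signals near background. Comparisons with control males at 1 day rest on that value for these probes. On any other array at most 645 tested probes held 1 shared value, but replaced values can also differ between probes. Replaced values of either kind made up 60.74% of the non-control probes on control 1 day replicate 5. The median over the 60 arrays was 21.01%, and RDX 6 month replicate 2 had 30.86%. The number of arrays limits the precision of every value. Over the 55 arrays without the outlying ones, the median within-group SD of a probe was 0.65 on the log2 scale, or 1.57-fold. The main fits used all 60 arrays, so this SD leaves out the spread that the 5 outlying arrays add.

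**Figure D1:**
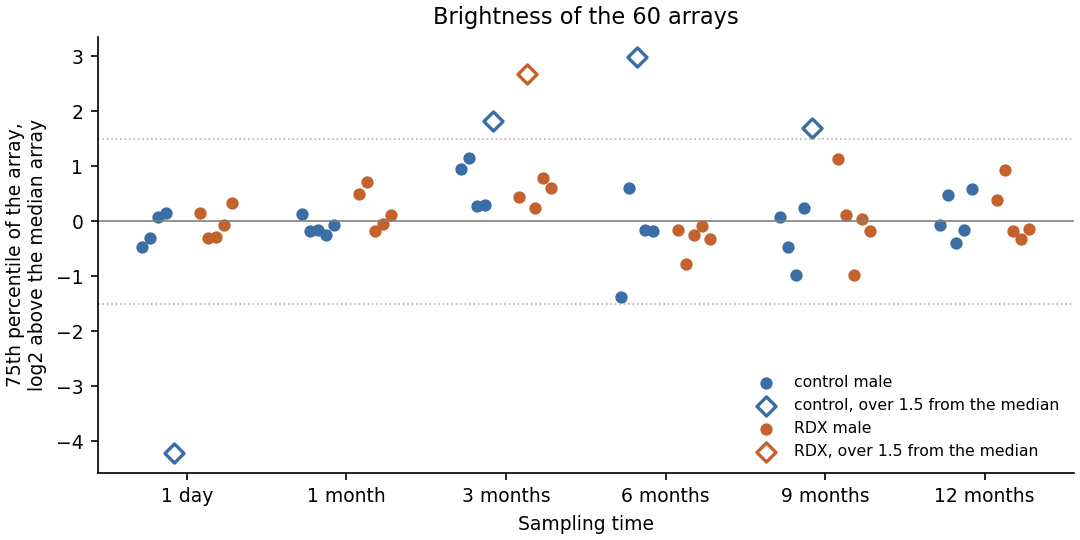
Each point is 1 array (60 in all, 5 per group), placed by sampling time on the x axis and by its 75th percentile in log2 units above the median array on the y axis, with control males in blue and RDX males in orange. Dotted lines mark 1.5 log2 units either side of the median array, and the 5 open diamonds beyond them run from -4.21 to 3.00.

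The first question was whether RDX in the water changed liver transcripts at any of the 6 times. No probe differed between exposed and control males beyond the spread among fish at any time. With limma, 0 of 10119 probes passed an adjusted p of 0.05 at 1 day, 1 month, 3 months, 6 months, 9 months and 12 months. An unadjusted p under 0.05 was found for 402, 236, 884, 816, 124 and 149 probes at these times, where independent probes that did not differ would give 506. Over the 11 alternatives, which also change the number of probes tested, these counts ran from 236 to 788, 142 to 506, 363 to 1204, 191 to 1016, 80 to 453 and 93 to 448 in the same order. The smallest adjusted p was 0.0963 at 3 months and 0.493 at 6 months, and lay between 0.999 and 1 at the other times. The median size of the difference over probes ran from 0.24 log2 units (1.18-fold, 12 months) to 0.43 (1.34-fold, 6 months).

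These comparisons were wide. The 95% interval of a difference at one time had a median half-width of 1.02 to 1.03 log2 units, about 2.04-fold, and lay wholly within 2-fold of no difference for 21.7% (6 months) to 28.4% (12 months) of probes. In simulated data with 200 changed probes of 10119, a 2-fold change at 1 time was recovered for 0.5% to 12.5% of them and a 4-fold change for 49.5% to 63% of them, so a 2-fold change at a single time was mostly not detectable with 5 arrays a group. Without the 5 arrays of outlying brightness, the probes with an unadjusted p under 0.05 numbered 419 at 3 months and 348 at 6 months. At 3 months a call appeared under 3 of the 11 alternatives. UF_Ppr_AF_100388 (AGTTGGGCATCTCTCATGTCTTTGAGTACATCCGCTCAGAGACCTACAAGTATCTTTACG), a probe singled out after its values were seen, was 2.41-fold lower in RDX males after normexp correction (limma adjusted p = 0.0257) and 2.52-fold lower with array weights (adjusted p = 0.0272), against an adjusted p of 0.0963 in the chosen setting. Its values at 3 months were 0.31 to 1.03 in control males and -1.06 to -0.11 in RDX males (scaled log2). At 1 day they were -1.07 to -0.34 and -1.43 to -0.29. The control males at 3 months thus stood above both 1 day groups, and the RDX males did not. UF_Ppr_AF_106628 (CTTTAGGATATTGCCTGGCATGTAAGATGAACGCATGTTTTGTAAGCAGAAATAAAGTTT), also named after its values were seen, was higher in RDX males with array weights (limma adjusted p = 0.0265) and without the 5 arrays (adjusted p = 0.0339), against an adjusted p of 0.379. It was well above background on 5 of 5 RDX arrays and 1 of 5 control arrays at 3 months, so no fold is given. In every other group it was so on 0 or 1 of 5 arrays. It met the background filter only through the group in which it was higher, so its calls are not independent of the filter.

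Averaged over the 6 times, no probe differed between exposed and control livers beyond the spread among fish either. With limma, 0 of 10119 probes passed for the mean difference, and 238 had an unadjusted p under 0.05. The 95% interval of the mean difference had a median half-width of 0.42 log2 units (1.34-fold), and it lay within 2-fold of no difference for 86.9% of probes and within 4-fold for 99.2%. In simulated data, a 2-fold change shared by all times was recovered for 73.5% of 200 changed probes and a 4-fold change for 99%. The probes with the smallest p in each direction did not pass and all had an adjusted p of 0.999. UF_Ppr_AF_107846 (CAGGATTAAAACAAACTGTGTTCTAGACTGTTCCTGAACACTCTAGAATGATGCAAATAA) had a mean difference of 0.39 ± 0.11 log2 units (SE), above 0 at 6 of 6 times. UF_Ppr_AF_116385 (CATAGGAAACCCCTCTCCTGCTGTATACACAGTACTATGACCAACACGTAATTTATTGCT) had 1.16 ± 0.36, above 0 at 4 of 6 times. This probe was saturated on 5 of the 60 arrays and left out as not uniform on 8, so that 2 control and 3 RDX spots were used at 6 months. UF_Ppr_AF_102357 (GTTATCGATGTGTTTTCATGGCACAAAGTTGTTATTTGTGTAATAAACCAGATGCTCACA) had -0.60 ± 0.16, and UF_Ppr_AF_116902 (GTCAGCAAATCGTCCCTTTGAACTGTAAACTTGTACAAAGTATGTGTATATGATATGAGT) had -0.56 ± 0.15, both below 0 at 6 of 6 times.

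The RDX differences at one time were little correlated with those at another. Across probes, which are not independent replicates, Pearson's r between the differences at 2 times ran from -0.226 to 0.165 over the 15 pairs of times, with a mean of -0.0207. A limma test of whether the RDX difference varied with time called 0 of 10119 probes (331 at an unadjusted p under 0.05), and a test of a difference at any time called 0 (268 at an unadjusted p under 0.05). In simulated data, a 4-fold change of 200 probes in 1 group was recovered for 26% of them by the first test and for 32.5% by the second.

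Sampling time set the background against which exposure was read, and transcript levels in unexposed livers differed between sampling times. Collection or RNA handling shared by the fish of 1 time cannot be told apart from a change in the fish. In control males, 920 of 10119 probes varied with time (limma F-test over the 6 times, adjusted p under 0.05), with 334 to 1407 when 1 array was left out and 2160 with array weights. In the chosen setting most calls against 1 day were at 1 month. Between 1 day and 1 month, 280 probes passed, of which 115 were higher and 165 lower at 1 month. At 3 months 2 probes passed (0 to 576 when 1 array was left out) and at 9 months 1 did (0 to 21). Without the filter on dim probes 2480 passed at 3 months, against 173 at 1 month. Most of the 2480 were lower, and this setting adds probes that failed the background filter. The mean 75th percentile of the arrays was 10.32, 11.17 and 12.18 (log2) in control males at 1 day, 1 month and 3 months. Whether brightness or values near background gave these calls was not tested. At 6 and 12 months 0 passed, with 1610 and 711 probes at an unadjusted p under 0.05.

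Of the 4 probes named for time in control males, UF_Ppr_AF_102760 (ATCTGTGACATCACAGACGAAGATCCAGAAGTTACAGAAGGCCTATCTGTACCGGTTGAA) fell 3.08-fold at 1 month, from -1.56 ± 0.18 to -3.18 ± 0.80 (log2, mean ± SD, n = 5 each; limma adjusted p = 0.00359). UF_Ppr_AF_116918 (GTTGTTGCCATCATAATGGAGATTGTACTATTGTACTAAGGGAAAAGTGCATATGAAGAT) fell from -1.19 ± 1.14 to -5.31 ± 0.57 (limma adjusted p = 0.00359). It was well above background on 4 of 5 control arrays at 1 day and 1 of 5 at 1 month, and on 5 of 5 and 2 of 5 RDX arrays, so the size of its fall rests on values near background and no fold is given. Its log2 change was -4.12, and -4.47 to -2.07 over the alternatives, the smallest with normexp correction, with limma adjusted p-values of 0.000445 to 0.0423. UF_Ppr_AF_102760 and UF_Ppr_AF_116918 held the shared value on control 1 day replicate 5, and without that array both still passed, at log2 changes of -1.65 and -4.24 (limma adjusted p = 0.0111 and 0.0106). UF_Ppr_AF_117739 (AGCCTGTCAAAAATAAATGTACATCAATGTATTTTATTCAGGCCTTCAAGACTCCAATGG) rose 3.28-fold, from 2.08 ± 0.87 to 3.79 ± 0.43 (limma adjusted p = 0.0281). UF_Ppr_AF_118252 (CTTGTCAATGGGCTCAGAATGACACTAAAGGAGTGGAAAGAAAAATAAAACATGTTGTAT) varied over the 6 times (limma F-test adjusted p = 4.0e-05) but did not pass at 1 month alone, at -0.31 ± 1.62 and 1.18 ± 0.75 (adjusted p = 0.241), and it too held the shared value on control 1 day replicate 5. The same 4 probes in RDX males differed in the same direction between 1 day and 1 month, UF_Ppr_AF_102760 by 3.81-fold lower (limma adjusted p = 0.000165), UF_Ppr_AF_117739 by 4.23-fold higher (0.00351), UF_Ppr_AF_118252 by 6.19-fold higher (0.0133), and UF_Ppr_AF_116918 lower (0.00703). UF_Ppr_AF_102760 did not pass in control males after quantile normalization, where its log2 change went from -1.62 to -1.002 (limma adjusted p = 0.202). Neither it nor UF_Ppr_AF_117739 passed in a fit of only the 2 groups, with log2 changes of -1.62 and 1.71 as before (adjusted p = 0.117 and 0.126). UF_Ppr_AF_117739 also lost its call, at log2 changes of 1.46 to 1.78 and limma adjusted p-values of 0.0607 to 0.08, when any 1 of control 1 month replicates 2, 3 and 4 or control 1 day replicates 1, 2 and 4 was left out.

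The few probes called in control males at other times were chosen after their values were seen. The call of UF_Ppr_AF_100388 rests on the same 5 control arrays at 3 months as the RDX difference given for it above. At 3 months UF_Ppr_AF_100388, named above, was 2.77-fold higher than at 1 day and UF_Ppr_AF_103064 (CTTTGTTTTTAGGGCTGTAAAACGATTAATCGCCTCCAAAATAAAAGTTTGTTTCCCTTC) lower, both with a limma adjusted p of 0.00652. The latter was well above background on 2 of 5 arrays at 1 day and 0 of 5 at 3 months, so no fold is given. Its highest value at 1 day was the shared value of control 1 day replicate 5, and without that array it did not pass (adjusted p = 0.105). Its log2 change was then -2.93 in place of -3.39, and both rest on values near background. At 9 months UF_Ppr_AF_114187 (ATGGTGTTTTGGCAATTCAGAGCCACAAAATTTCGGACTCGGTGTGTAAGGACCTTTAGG) was lower (limma adjusted p = 0.0126), and was well above background on 4 of 5 arrays at 1 day and 1 of 5 at 9 months. It held the same shared value, and without that array it did not pass either (adjusted p = 0.19), with a log2 change of -2.42 in place of -2.70. Without the 5 arrays of outlying brightness, or with slide as a block, 0 probes passed in limma at either time (1137 and 719 at an unadjusted p under 0.05 without the 5 arrays, 1341 and 792 with the block). The 3 changes kept their direction. Without the 5 arrays and with the block, the log2 change of UF_Ppr_AF_100388 at 3 months was 1.405 and 1.282 (1.47 before). That of UF_Ppr_AF_103064 was -2.745 and -2.875 (-3.39 before), and that of UF_Ppr_AF_114187 at 9 months -2.47 and -2.287 (-2.70 before). The sizes of the latter 2 rest on values near background. Over all alternative and leave-out fits, UF_Ppr_AF_100388 ran from 1.282 to 1.831, UF_Ppr_AF_103064 from -3.787 to -0.979 and UF_Ppr_AF_114187 from -2.941 to -0.82.

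The number of 1 month calls in control males, and the balance of higher and lower probes, moved with the processing. Higher and lower probes numbered 195 and 103 after quantile normalization, 148 and 78 after scaling by the median, 231 and 136 after normexp correction, and 187 and 207 without the 5 arrays. The median change over all probes was -0.15 log2 units with the 75th percentile and 0.14 with quantile normalization, so higher and lower are relative to the scaling point. The count was 23 in a fit of only the 2 groups and 304 with slide as a block. It ran from 52 (without control 1 month replicate 2) to 594 (without control 1 day replicate 3) when 1 array was left out.

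RDX males, which were separate fish, changed at 1 month too. In them 471 probes passed between 1 day and 1 month, 144 higher and 327 lower, and with limma 0 passed at 3, 6, 9 and 12 months (1523, 157, 510 and 414 at an unadjusted p under 0.05). The time comparisons in RDX males, and every comparison of the 2 arms over time, were added after the data were seen. The 1 month count was 236 with slide as a block and 1006 without the 5 arrays of outlying brightness. Of the 920 probes that varied with time in control males, 1 month was the highest or lowest of the 6 times for 71.6% in control males and 70.3% in RDX males, where times that were alike would give 33.3%.

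The same probes moved in both arms. Of the 280 control calls, 279 had the same sign in RDX males, and of the 471 RDX calls, 470 had the same sign in control males, as did 72.3% of all 10119 probes. Both arms called 157 probes in the same direction, 52 higher and 105 lower, where independent lists would share 1.64 and 5.33, and 0 probes were called in opposite directions. Pearson's r across probes was 0.595 at 1 month and 0.344, 0.078, 0.29 and 0.295 for the changes from 1 day to 3, 6, 9 and 12 months. With slide as a block, r at 1 month was 0.526 and 98 probes were called in both arms (3.77 by chance). Without the 5 arrays, r was 0.622 and 264 probes were shared (19.9 by chance). No slide held 2 arrays of both a 1 month group and the 1 day group of its arm, so the calls could not be repeated within a slide. In control males 3 slides held at least 1 array of both groups, and in RDX males 0 did. The RDX comparison was therefore wholly between slides, and the block could adjust it only through the other groups. Set against the mean of the other 5 times, 1 month differed in 1123 probes in control males (585 higher, 538 lower) and in 934 in RDX males (375 higher, 559 lower), with 573 called in both in the same direction and an r of 0.701.

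**Figure D2:**
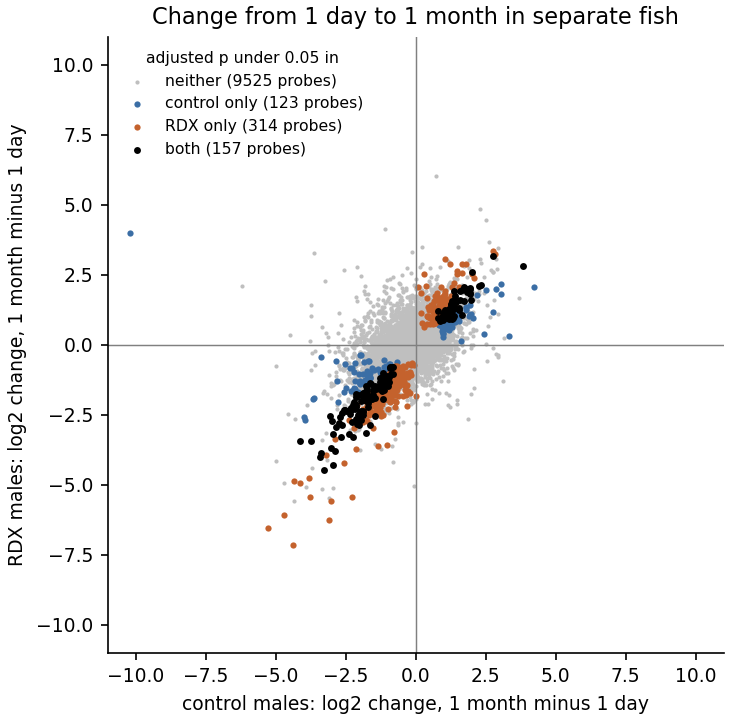
Each point is 1 of 10119 probes, placed by its log2 change from 1 day to 1 month in control males (x axis) and in RDX males (y axis), with colours for probes called by limma in neither arm, in control males alone, in RDX males alone or in both. The 157 black points called in both arms lie to the lower left and upper right of 0, and the lone blue point farthest to the left is UF_Ppr_AF_103241, which was well above background on none of the 3 control arrays used for it at 1 month.

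A score per fish showed the 1 month change in single livers. The score was the mean of the probes called higher at 1 month minus the mean of those called lower, with the probes taken from the other arm. Control males scored 2.00 ± 0.59 at 1 month and -0.48 ± 0.71 at 1 day (mean ± SD, n = 5 each; exact two-sided permutation p = 0.00794, the smallest that 5 against 5 allows). RDX males scored 2.10 ± 0.59 at 1 month and -0.83 ± 0.57 at 1 day (n = 5 each; exact two-sided permutation p = 0.00794). Over the 10 comparisons of 1 month with another time, the exact permutation p was 0.00794 in all but RDX males at 3 months, which scored 0.62 ± 0.80 (n = 5; exact permutation p = 0.0159), and the Benjamini-Hochberg adjusted values were 0.00882 and 0.0159. Fish of 1 month shared 6 slides with fish of other times, and these were compared after the mean score of each arm over its other 5 times had been subtracted. On all 6 slides each 1 month fish then scored above each other fish, by means that differed by 1.93 to 3.11 log2 units.

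**Figure D3:**
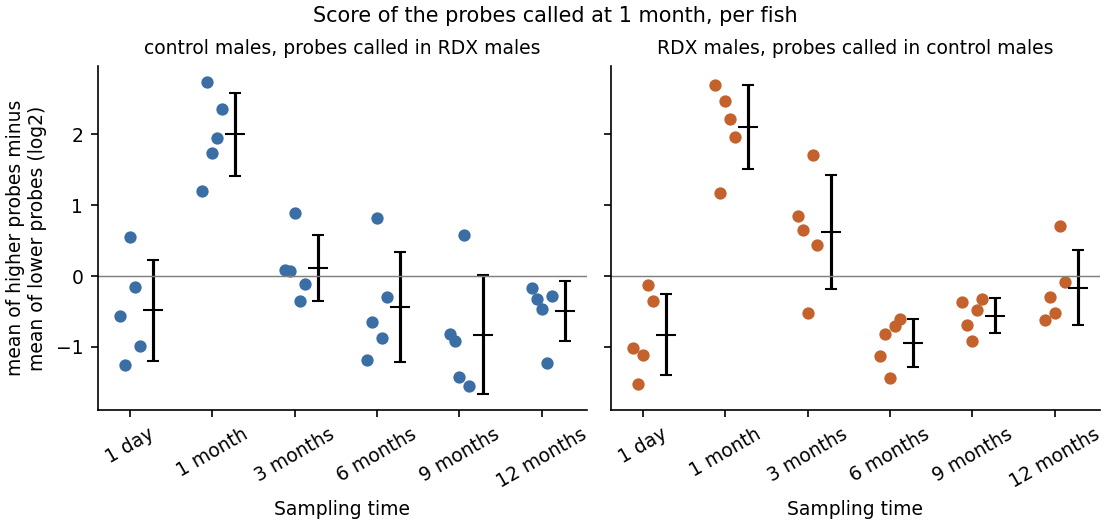
Each point is the score of 1 male (y axis, log2 units) at its sampling time (x axis), with control males on the left scored on the probes called in RDX males and RDX males on the right scored on the probes called in control males. Bars are the mean ± SD of 5 fish, and the 1 month fish run from 1.20 to 2.74 in control males and from 1.17 to 2.69 in RDX males.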

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

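All tests in this part except the within-slide comparison of the score were chosen after the results they bear on had been seen. Values that stood apart within a group of 5 were found by Dixon's test, which met 8 of the 96 groups tested, where chance gives 4.8, and 7 of the 8 were measures of the arrays.

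Array measures stood apart as follows. The array of control 1 day replicate 5 lay at -4.21 log2 units from the median array in brightness, had 20.5% of its probes well above background (56.9% on the nearest array of its group) and had a mean signal of 909.1 on its negative controls, where the median array had 235.9 and the highest other array 368.4. That mean rested in large part, though not wholly, on 1 spot of 39627, and the median of its negative controls was 279.7, against 231.3 on the median array. RDX 3 month replicate 2 was brighter than the median array by 2.68 log2 units. The negative controls read 191.6 in control 6 month replicate 3, 217.5 in RDX 3 month replicate 5 and 368.4 in RDX 6 month replicate 1, each apart from the other 4 arrays of its group. Negative controls also differed between slides. All arrays on the slide of RDX 6 month replicate 1 read 339.5 to 368.4. The other arrays on the slide of control 6 month replicate 3 read 152.7 to 157.9, so that array was the highest there. The score of the probes called at 1 month was -1.22 in control 12 month replicate 4, against -0.46 in the nearest fish of its group.

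The 5 arrays of outlying brightness went with more small p-values for RDX against control at 3 and 6 months, but not at every time. At 3 and 6 months, 884 and 816 probes had an unadjusted p under 0.05. Other splits of the same arrays gave medians of 900 and 936, and 54 and 64 of 100 splits, the real one included, reached the real counts, so these are no surplus for exposure. Without the 5 arrays the counts were 419 and 348 (506 for independent probes that did not differ), so these arrays may have raised them. At 1 day the count went from 402 to 368, and at 1, 9 and 12 months it rose from 236, 124 and 149 to 506, 255 and 298 without the 5 arrays. A brighter scanner setting would raise the spike-in RNAs too, but the highest spike-in signal of the 4 bright arrays was 0.206 log2 units above the median array, which argues against it for those 4. In control 1 day replicate 5 the 2 usable spike-in RNAs lay at -3.51 log2 units from the median array, below the -1.59 to 1.84 of the arrays of usual brightness. The amount of liver RNA is therefore argued against as the whole cause of its -4.21, as spike-ins would not fall with it. Their fall would go with a dimmer scanner setting. Such a setting would also lower the local background and the signal of the negative controls over it, which were 1.07 and 1.52 times those of the median array, so it is argued against as the whole cause. Labelling and hybridization of this array, and the amount and quality of the RNA on the 4 bright arrays, stay open as untested, and no biological explanation was tested for the 5.

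The change of livers at 1 month was found in both arms, which share no fish. Differences between slides are argued against as its whole cause by 98 probes called in both arms with slide as a block (3.77 by chance) and by the 6 slides, of 6 with such fish, on which the 1 month fish had the higher mean score. The arrays of outlying brightness are argued against by the 264 probes shared without them (19.9 by chance). Collection or RNA handling shared by the fish of one time would also give the correlation of 0.595 between the arms, and cannot be told apart from age, season or time in the tanks, because the labels give no collection details and each time was sampled in both arms. Time in the tanks, age and season therefore stay open as untested explanations.

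Other splits of the same arrays bear on each count of calls, with 100 splits drawn for each, the real one included. The smallest share that 100 splits can give is 1 of 100, and the shares were not adjusted for the number of counts. By the number of calls, chance is made unlikely but not excluded for 6 counts, each reached by 1 of 100 splits, the real one. These were control males at 1 month against 1 day (280, highest other split 179), RDX males at 1 month against 1 day (471, 272), 1 month against the other times in control males (1123, 691) and in RDX males (934, 71), and time in control males (920, 150) and in RDX males (473, 2). The number of calls does not make chance unlikely for control males at 3 months (2 calls, reached by 16 of 100 splits, highest other 423) and at 9 months (1 call, 14 of 100, highest other 22). Every count of 0 was reached by 100 of 100 splits, as any count reaches 0, so these say nothing of smaller differences. The number of probes at an unadjusted p under 0.05 ranked some comparisons otherwise. In control males it was reached by 3 of 100 splits at 1 month (1619, highest other split 1641), at 3 months (1912, 2494) and at 9 months (960, 1108), by 31 at 6 months and by 18 at 12 months. In RDX males it was reached by 1 of 100 at 1 month (1693, 1583) and at 3 months (1523, 1489), by 5 at 9 months (510, 638), by 13 at 12 months and by 87 at 6 months. Differences from 1 day at 3 and 9 months therefore stay possible in both arms beside the few or 0 calls. For the other 4 of the 6 counts it was reached by the real split alone, and for RDX against control by 39 to 78 of 100 splits at single times and by 90 for the mean. For RDX against control, the highest other split called 12 probes at 1 day, 1 at 1 month, 62 at 3 months, 66 at 6 months and 0 at 9 and 12 months and for the mean over times, and 4 for both the interaction and the test at any time. Against 1 day, it called 202 at 6 months and 2 at 12 months in control males, and 5, 19, 0 and 0 at 3, 6, 9 and 12 months in RDX males. Some splits called many times the real count, such as 423 against 2 in control males at 3 months and 202 against 0 at 6 months. They may reflect differences among these arrays other than their groups. Array brightness went with 51.9% of the variance of the first principal component, which held 19.6% of all variance after scaling. Its part in these splits was not tested.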

How the results depend on the processing

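Added after the data were seen were the fits without the 5 arrays of outlying brightness, those with non-uniform spots kept, and all alternatives of the comparisons that were themselves added. No paired analysis was possible because the labels give no replicate numbers that pair fish. No alternative reversed any of the 8 probes named by the rule, nor UF_Ppr_AF_100388, UF_Ppr_AF_103064, UF_Ppr_AF_103241, UF_Ppr_AF_106628 or UF_Ppr_AF_114187 in the comparisons for which they are named. For RDX against control, all 11 alternatives also gave 0 calls in limma at 1 day, 6, 9 and 12 months, and all 10 did for the mean over times, the interaction and the test at any time (151 to 312, 217 to 479 and 167 to 429 at an unadjusted p under 0.05; the single times are in the report). Calls appeared at 1 month in a fit of only the groups compared (1) and at 3 months with normexp (1), array weights (2) and without the 5 arrays (1). In control males, the 280 calls at 1 month became 173 without the filter on dim probes, 1121 with array weights and 23 in a fit of only the groups compared. The 2 calls at 3 months became 9 with normexp, 2480 without the filter (2421 of them lower), 1 with the filter of 54 arrays, 110 with array weights, and 0 with slide as a block, without the 5 arrays and in a fit of only the groups compared. The 0 calls at 6 months became 1 with quantile normalization, 4 with the filter of 54 arrays and 1 with slide as a block. The 1 call at 9 months became 0 with normexp, quantile normalization, the filter of 54 arrays, slide as a block and without the 5 arrays, and 2 in a fit of only the groups compared. Time in control males (920) became 2160 with array weights. In RDX males, the 471 calls at 1 month became 294 with normexp, 298 with quantile normalization, 236 with slide as a block, 1327 with array weights and 1006 without the 5 arrays. The 0 calls at 3 months became 137 with array weights and 2 without the 5 arrays. Time in RDX males (473) became 283 with quantile normalization, 314 with the median, 297 without the filter, 287 with slide as a block, 1926 with array weights and 1201 without the 5 arrays. With array weights and without the 5 arrays, 1 month against the other times became 2408 and 1960 in control males (from 1123) and 1990 and 1726 in RDX males (from 934). The 157 probes called in both arms became 102 with quantile normalization, 99 without the filter, 98 with slide as a block, 599 with array weights and 264 without the 5 arrays. The filters and smaller fits test fewer or noisier probes or fewer arrays; otherwise the cause was not tested.

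Leaving out 1 array at a time, RDX against control gave 0 to 1 calls at 1 day (1 without control 1 day replicate 4), 0 at 1 month, 0 to 1 at 3 months (1 without control 3 month replicate 4, RDX 3 month replicate 4 or RDX 3 month replicate 5), 0 to 1 at 6 months (1 without control 6 month replicate 4), 0 at 9 and 12 months and for the mean, and 0 to 1 for the interaction and the test at any time (1 without control 3 month replicate 4). In control males against 1 day, the range was 52 to 594 at 1 month. It was 52, 184 and 126 without 1 month replicates 2, 3 and 5, and 164, 86, 594 and 114 without 1 day replicates 1, 2, 3 and 5. At 3 months it was 0 to 576 (576 and 1 without 1 day replicates 3 and 5, 76 and 0 without 3 month replicates 4 and 5). At 6 months it was 0 to 39 (4 and 1 without 1 day replicates 2 and 4, 9, 39 and 1 without 6 month replicates 1, 2 and 5). At 9 months it was 0 to 21 (21, 2, 2, 4 and 0 without 1 day replicates 1 to 5 in that order, 0, 4 and 4 without 9 month replicates 2, 3 and 4). At 12 months it was 0 to 2 (2 without 1 day replicate 4). Time in control males gave 334 to 1407 (334, 612 and 484 without 1 month replicates 2, 3 and 5, 1407 without 6 month replicate 2). In RDX males, 1 month gave 235 to 487 (283, 290 and 299 without 1 month replicates 1, 3 and 4, 295, 288 and 235 without 1 day replicates 1, 2 and 3), 3 months 0 to 67 (67 without 3 month replicate 3), 6, 9 and 12 months 0, and time 217 to 669 (234, 239 and 217 without 1 month replicates 1, 3 and 4). Against the other times, 1 month gave 384 to 1403 in control males (384 and 603 without 1 month replicates 2 and 5) and 451 to 1076 in RDX males (451, 546 and 508 without 1 month replicates 1, 3 and 4). Probes called in both arms gave 40 to 249 (40 and 78 without control 1 month replicates 2 and 5, 103, 56, 249 and 78 without control 1 day replicates 1, 2, 3 and 5). The mean correlation of RDX differences between times stayed between -0.032 and -0.0033 over 6 alternatives. Signal over background limits these arrays most on control 1 day replicate 5, where 20.5% of probes were well above background.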

Other observations

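All tests in this part were chosen after the results they bear on had been seen, and so were the probes named here.

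Some groups of probes differed widely between single livers, also within a group. Among the 200 most variable of the tested probes on the 55 arrays of usual brightness, 3 clusters moved together from fish to fish. The first held 15 probes of 15 contigs with a mean pairwise r of 0.841, and the within-group SD of its mean level was 2.57 log2 units, with 36.3% of the variance between the 12 groups and 76.2% of its spots well above background. Exposed and control males did not differ detectably in it (-0.21 ± 3.05 in 29 RDX males and 0.26 ± 2.72 in 26 control males, mean ± SD; permutation p = 0.554, adjusted 0.696 over the 3 clusters). The second cluster (14 probes, within-group SD 1.99, 46.9% of the variance between groups, 81.2% of spots well above background) correlated with array brightness over 55 fish (Pearson's r = -0.583, permutation p = 1e-05, the smallest that the permutations can give; Spearman's rho = -0.58, permutation p = 2e-05; adjusted 3e-05 and 6e-05 over the 3 clusters; r = -0.542 without the 2 arrays farthest from the median). The third (9 probes, within-group SD 2.08) had 32.5% of its variance between groups and 44.7% of its spots well above background. Spots at background make these SDs inexact.

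A set of probes was high in some fish and low in others with a gap between, here called on and off. On the 55 arrays, 30 of 10119 probes had a gap of at least 3 log2 units with at least 6 fish on either side, a limit chosen after several had been looked at. UF_Ppr_AF_119087 (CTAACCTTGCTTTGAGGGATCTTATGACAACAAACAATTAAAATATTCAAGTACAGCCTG) was off in 29 fish (-6.16 ± 0.79, log2, mean ± SD) and on in 25 (4.69 ± 0.49), and UF_Ppr_AF_110866 (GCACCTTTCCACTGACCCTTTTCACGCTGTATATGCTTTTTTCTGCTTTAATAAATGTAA) was off in 31 (-5.77 ± 0.86) and on in 24 (4.42 ± 0.52). The median share of spots well above background was 0% in the off state and 100% in the on state, so no fold between the states is given. The share in the off state ran from 0% to 100% over the 30 probes, so for some of them off means lower and not at background. The 30 probes came from 30 contigs or tags, and the states of different probes were mostly unrelated (median r 0.0075 over 325 pairs of the 26 probes measured on all 55 arrays, highest 0.773).

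Poor arrays or RNA are argued against as the cause of the on and off states, because the number of off probes per fish (1 to 12 of 26) varied 1.19 times as much as independent probes would give, within the 0.685 to 1.41 of shuffled fish. Slides and exposure are argued against as the whole cause, since all 30 probes had both states on at least 2 slides and all 30 had both states among control males. With exposure, the smallest p over the 30 probes was 0.0156 (Fisher's exact test, adjusted 0.468), for UF_Ppr_AF_119087, on in 18 of 29 RDX males and 7 of 25 control males. A candidate explanation is a sequence or gene difference between fish under the probe, which would give 2 states and unrelated probes, but the 30 gaps alone cannot tell it from an RNA that is switched on in some livers, and no genotypes were used here.

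One such probe lay behind 2 values of the comparisons. UF_Ppr_AF_103241 (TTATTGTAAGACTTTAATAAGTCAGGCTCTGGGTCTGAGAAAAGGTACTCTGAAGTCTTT) was the single control call at 1 month with the opposite sign in RDX males, lower in control males (limma adjusted p = 0.034) and not passing in RDX males (adjusted p = 0.467). The call rested on 3 control males at 1 month, all off (-6.89 to -4.86, log2) and 0 of 3 well above background, and 4 at 1 day, all on (2.85 to 5.19), so no fold is given. The spots of the other 2 control males at 1 month were well above background but left out as not uniform, and with such spots kept the probe did not pass (adjusted p = 0.144). It was also the 1 probe called, as higher, for RDX against control at 1 month in a fit of only those groups (limma adjusted p = 0.00414), against the same 3 control males, with an adjusted p of 0.999 in the fit of all groups.

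A further hypothesis was that the 2 arms followed a shared course over all 6 times and not at 1 month alone. Each time's difference from the other 5 times was correlated across probes between the arms. The mean r was 0.365 for the same times and -0.0676 for different times, and 1 of the 720 ways to match the times of the arms, the real one, reached it (exact one-sided p = 0.00139, the smallest possible; highest other matching 0.354). Of the 6 times, 4 correlated best with their own time in the other arm. The closeness of the second matching and the r of 0.701 at 1 month leave open how much the other times add.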
